A study of Mus musculus with 32 samples.

How the data were processed

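Bone and gingiva were collected from 9-week-old male C57BL/6J mice in 4 treatment groups, and poly(A) RNA was extracted with TRIzol and a column kit and sequenced, per the labels' protocols. Each tissue had 16 libraries, 4 per group. The deposited tables hold estimated counts per gene as whole numbers, which the authors made before deposit. Trimmomatic 0.39, FastQC 0.11.9, HISAT2 2.2.1, StringTie 2.1.7 and DESeq2 1.32.0 and the GRCm39 build are named, per the submitters' processing notes, without their order or settings. How reads were assigned to genes and whether strand was used are not given in the sources used here, so overlapping genes and near-identical copies can share reads. Nothing in the labels states that libraries of the same number come from 1 animal, and p-values measure the spread between these libraries. The trauma columns carry the letters CR, read here as the composite resin that the treatment label names.

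Total counts were 38163979 to 70793037 per bone library and 36913075 to 50740393 per gingiva library, with 22185 to 26087 and 22974 to 24358 genes above 0. Both tables list the same 55359 Ensembl gene identifiers. Of these 52083 matched a symbol in the GENCODE M21 gene table by identifier without its version, and 3276 did not, which took at most 0.215% of the counts in a bone library and 0.409% in a gingiva library. That table belongs to another build than the deposited counts, so no coordinates are given. No 2 libraries held identical values, and no pair of libraries of a group differed by as little as sampling noise.

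Counts were analysed in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 21205 in bone, 21129 with a symbol, and 20143 in gingiva, 20082 with a symbol. Libraries were scaled by TMM. All 16 libraries of a tissue entered 1 fit, so that the groups shared 1 estimate of the spread. The 6 comparisons per tissue were Li against Co, Tra against Co, LiTra against Co, LiTra against Li, LiTra against Tra, and the interaction, the ligature effect with overload minus that without. A fit of all 32 libraries tested differences of effect between the tissues over 22559 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. CPM values use the TMM-scaled library sizes. For a group with 0 counts in all libraries a fold is given as a bound against 3 counts over the group. Counting error alone is covered by such bounds.

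Gene lists for cell types and pathways, 34 in all with 579 genes, were fixed before the data were examined, as were the groups, the fits, the rule for named genes and all alternatives except those named below as chosen later. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1. Its correlation was preset at 0.01 or estimated per list, and fry tested lists against no change. No list was called by camera with an estimated correlation in any comparison. Fry called 9, 13 and 10 lists in bone and 10, 19 and 22 in gingiva for Li against Co, LiTra against Co and LiTra against Tra, and 0 in the other comparisons. A list score per library is the mean over members of the log2 CPM minus the gene's mean over libraries. Genes were named by a rule: in each comparison the 6 with the largest increase and the 6 with the largest decrease among called genes whose libraries did not overlap between the groups and whose mean log2 CPM was at least 1, up to 4 members of each list with the smallest p, and 13 genes in every comparison (Acp5, Ctsk, Tnfsf11, Tnfrsf11b, Il1b, Il6, Tnf, Mmp13, S100a8, Postn, Col1a1, Bglap and Sost). For tissue differences 4 were taken each way. Sost was below the filter in gingiva. Some genes that the rule takes are not reported here.

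Alternatives were DESeq2's size factors or library totals in place of TMM, no filter on low counts or a stricter filter (CPM over 1 in at least 4 libraries), DESeq2 1.42.0, limma-voom with quality weights, the replicate number as a block, fits of the compared groups alone, a fold change of at least 2, an adjusted p under 0.01, genes with a symbol alone, and leaving out each library in turn. Chosen after seeing the data were a fit without the 3 bone libraries in which 10 genes took most of the counts (Co 3, Tra 3 and LiTra 1), a fit with each library's trend on transcript GC content removed (lowess, span 0.3), and lists of circadian clock, heat shock and nasal gland genes.

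The fits were tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. In bone 28% of the 2-fold and 79% of the 4-fold genes were recovered for Li against Co among 20697 genes, 29% and 78% for Tra against Co among 20698, 31% and 83% for LiTra against Li among 20714, and 4% and 57% for the interaction among 20714. In gingiva these were 58% and 96% among 19646, 57% and 99% among 19639, 61% and 96% among 19662, and 17% and 87% among 19662. Between 3 and 12 unchanged genes were called per comparison. A simulated list of 20 raised genes had a camera p of 2.1e-29 in bone and 3.1e-40 in gingiva. Of 100 random lists 1 and 0 fell under 0.05, with correlated lists untested. Figures used Python 3.11.15 and matplotlib 3.10.9.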

Results

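Poly(A) RNA was sequenced from bone and gingiva of 9-week-old male C57BL/6J mice, an inbred laboratory strain. Control mice (Co) were untreated. In ligature mice (Li) a silk thread was tied round the left second upper molar, a standard way to induce periodontitis. In trauma mice (Tra) composite resin was built up on the biting surface of that tooth to overload it, and a combined group (LiTra) received both. Each of the 4 groups had 4 libraries per tissue, 32 in all, and the labels gave no time between treatment and sampling. Per the series title, the question was whether occlusal overload adds to bone resorption in ligature-induced periodontitis through gene expression in bone. Library totals were 38163979 to 70793037 counts in bone and 36913075 to 50740393 in gingiva. All fold changes below are log2 ± SE from edgeR with 4 libraries per group. Levels are CPM, counts scaled to a common library size after TMM, as mean ± SD (n = 4).

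A few genes took very uneven shares of the bone counts. Transcripts of a nasal gland list, written after the data were seen, took 48.6% of the counts in Co 3, 35.1% in Tra 3 and 52.1% in LiTra 1, with 24.6% in Li 2, 15.2% in Co 4 and 6.93% in Tra 1. Bpifb9b, a gene of this list, took 30.4% of the counts in Co 3 and 32.5% in LiTra 1, and the odorant-binding protein gene Obp2a 8.59% in Tra 3. In Co 3, Tra 3 and LiTra 1 the 10 most abundant genes took 51.1%, 62.9% and 53.6% of the counts, and these libraries came from 3 different groups. Haemoglobin transcripts made up 1.36 to 4.43% of the counts in Co bone, 0.616 to 2.32% in Li, 0.505 to 4.92% in Tra and 0.203 to 0.525% in LiTra. In gingiva, Tra 2 held 2.93% nasal gland transcripts, and Li 1 had 0.246% haemoglobin.

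Li against Co asked what the ligature alone changed in bone. Saa3 (ENSMUSG00000040026.9), an acute-phase serum amyloid, rose from 2.07 ± 1.27 to 344 ± 145 CPM, a log2 change of 7.35 ± 0.62 (adjusted p = 9.5e-05). Mmp3 (5.71 ± 0.74), Il6 (4.80 ± 0.88), Prg4 (4.0 ± 0.53), Bdkrb1 (3.66 ± 0.57) and Ptgs2 (3.63 ± 0.67) also rose; they encode stromelysin, interleukin 6, lubricin, the inducible bradykinin receptor and the inducible cyclooxygenase (adjusted p 0.0021 to 0.0095). Ctsk (ENSMUSG00000028111.5), the main collagen-degrading protease of osteoclasts, went from 1135 ± 345 to 3300.0 ± 569.5 CPM (1.54 ± 0.29, adjusted p = 0.011), and Tnfsf11, which encodes the osteoclast differentiation factor RANKL, from 9.97 ± 3.42 to 28.2 ± 7.71 CPM (1.5 ± 0.28, adjusted p = 0.011). Mmp13 rose by 1.97 ± 0.31. Among the largest decreases were those of B cell genes, Fcmr (-2.46 ± 0.59), Tnfrsf13c (-2.30 ± 0.46), Ms4a1 (-2.24 ± 0.57), Cd22 (-2.12 ± 0.44) and H2-Ob (-2.08 ± 0.44). Acp5 and Il1b did not pass, at 1.02 ± 0.30 (adjusted p = 0.078) and 2.33 ± 0.62 (adjusted p = 0.053), nor did Tnfrsf11b (0.54 ± 0.26), Tnf (-0.29 ± 0.36), S100a8 (-0.63 ± 0.51), Postn (0.39 ± 0.39), Col1a1 (-0.02 ± 0.37), Bglap (-0.82 ± 0.31) or Sost (-0.34 ± 0.53).

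Osteoclast and matrix lists ranked higher. Of 19 osteoclast genes, 13 rose, 0 fell and 6 did not pass, and 17 were higher and 1 lower adjusted over the list alone. Osteoclast genes ranked higher (camera adjusted p = 2.0e-16, adjusted p = 0.361 with an estimated correlation), with Slc9b2 at 1.82 ± 0.27, Atp6v0d2 at 1.66 ± 0.26, Dcstamp at 1.86 ± 0.30 and Ocstamp at 1.85 ± 0.30. Of 18 genes of osteoclastogenic signals, 4 rose, 0 fell and 14 did not pass, and 6 were higher and 0 lower adjusted over the list alone. Genes of osteoclastogenic signals ranked higher (camera adjusted p = 3.9e-04, adjusted p = 0.361 with an estimated correlation), with Lif at 1.48 ± 0.27. Of 19 collagen and matrix assembly genes, 3 rose, 0 fell and 16 did not pass, and 10 were higher and 0 lower adjusted over the list alone. Collagen and matrix assembly genes ranked higher (camera adjusted p = 2.4e-08, adjusted p = 0.361 with an estimated correlation), with Vcan at 1.53 ± 0.22, Lox at 1.08 ± 0.18 and Fbn1 at 1.14 ± 0.21. Of 16 metalloproteinase and inhibitor genes, 4 rose, 0 fell and 12 did not pass, and 6 were higher and 1 lower adjusted over the list alone. Metalloproteinase and inhibitor genes ranked higher (camera adjusted p = 1.3e-05, adjusted p = 0.361 with an estimated correlation), with Timp1 at 2.08 ± 0.25 and Adamts4 at 2.66 ± 0.35.

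Of 19 chemokine genes, 3 rose, 1 fell and 15 did not pass, and 6 were higher and 1 lower adjusted over the list alone. Chemokine genes ranked higher (camera adjusted p = 1.7e-04, adjusted p = 0.361 with an estimated correlation), with Ccl9 at 1.61 ± 0.23 and Ccl2 at 3.11 ± 0.55. Cxcl12 was the chemokine gene that fell (-1.17 ± 0.30). Of 19 cytokine and receptor genes, 3 rose, 0 fell and 16 did not pass, and 6 were higher and 0 lower adjusted over the list alone. Cytokine and receptor genes ranked higher (camera adjusted p = 0.001, adjusted p = 0.361 with an estimated correlation). Of 17 endothelial genes, 2 rose, 0 fell and 15 did not pass, and 5 were higher and 0 lower adjusted over the list alone. Endothelial genes ranked higher (camera adjusted p = 6.4e-04, adjusted p = 0.587 with an estimated correlation), with Selp at 2.08 ± 0.31 and Sele at 1.74 ± 0.27. Selp and Sele encode adhesion molecules for leukocytes.

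Blood cell and fat lists ranked lower in Li bone. Of 22 B and plasma cell genes, 2 rose, 5 fell and 15 did not pass, and 2 were higher and 9 lower adjusted over the list alone. B and plasma cell genes ranked lower (camera adjusted p = 0.001, adjusted p = 0.361 with an estimated correlation), with Cd79b at -1.91 ± 0.45 and Pax5 at -2.07 ± 0.50. Sdc1 (1.54 ± 0.20) and Prdm1 (1.45 ± 0.27) rose, and Mzb1 did not. Of 22 T and NK cell genes, 0 rose, 0 fell and 22 did not pass, and 0 were higher and 1 lower adjusted over the list alone. T and NK cell genes ranked lower (camera adjusted p = 3.9e-04, adjusted p = 0.361 with an estimated correlation). Of 15 erythroid genes, 0 rose, 0 fell and 15 did not pass, and 0 were higher and 7 lower adjusted over the list alone. Erythroid genes ranked lower (camera adjusted p = 3.2e-07, adjusted p = 0.361 with an estimated correlation). The median log2 difference of erythroid genes was -1.22. Of 14 adipocyte genes, 0 rose, 1 fell and 13 did not pass, and 0 were higher and 1 lower adjusted over the list alone. Adipocyte genes ranked lower (camera adjusted p = 6.4e-04, adjusted p = 0.361 with an estimated correlation). Camera calls of the Schwann cell, cell cycle, hypoxia, immediate early gene, marrow neutrophil precursor, mechanical load, mitochondrially encoded and periodontal ligament lists were each lost when at least 1 library was left out, and these lists are not described here.

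Of 21205 genes tested in bone, 745 changed between Li and Co, 565 higher and 180 lower (edgeR, adjusted p from 9.5e-05). The count was 411 without Co 1, 202 without Co 4, 440 without Li 1, 432 without Li 2, 449 without Li 3, 345 without Li 4 and 1232 without Tra 3, and 1775 without Co 3, Tra 3 and LiTra 1 together. With library totals as the only scaling it was 5, and Saa3, Mmp3 and Il6 were the named genes still called; of the B cell genes named, Ms4a1 and Fcmr lost their calls in 11 and 7 of 16 fits that each left out 1 library, Cd22 and H2-Ob in 4 each and Tnfrsf13c in 2, and Ctsk and Tnfsf11 in 1 each.

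Tra against Co asked what the overload alone changed in bone. Ctsk went from 1135 ± 345 to 1419 ± 523 CPM (0.32 ± 0.29), Tnfsf11 from 9.97 ± 3.42 to 14.1 ± 4.22 CPM (0.50 ± 0.28) and Acp5 from 964 ± 325 to 945 ± 365 CPM (-0.03 ± 0.29), and none of these passed the test (adjusted p 0.59 to 0.984). Log2 differences that did not pass were also measured for the RANKL decoy receptor gene Tnfrsf11b (0.64 ± 0.26), Mmp13 (0.47 ± 0.30), Il6 (-0.44 ± 0.83), Tnf (-0.90 ± 0.36), S100a8 (-0.98 ± 0.52), the ligament matrix gene Postn (0.79 ± 0.39) and Sost (0.80 ± 0.53), the osteocyte inhibitor of Wnt signalling. No gene was called by edgeR (0 of 21205, with 2023 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0776), 160 by DESeq2 and 0 by limma-voom, and 1 gene was called by edgeR without Tra 2.

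Camera ranked the gene lists of this comparison against all other genes. Lists ranked higher in this comparison included periodontal ligament and tendon genes (14 tested, camera adjusted p = 7.6e-05, adjusted p = 0.645 with an estimated correlation) and skeletal muscle genes (20 tested, camera adjusted p = 1.5e-04, adjusted p = 0.758 with an estimated correlation). Ranked lower were neutrophil genes (18 tested, camera adjusted p = 2.1e-06, adjusted p = 0.645 with an estimated correlation) and marrow neutrophil precursor genes (13 tested, camera adjusted p = 9.8e-06, adjusted p = 0.645 with an estimated correlation). So were T and NK cell genes (22 tested, camera adjusted p = 1.2e-04, adjusted p = 0.645 with an estimated correlation) and B and plasma cell genes (22 tested, camera adjusted p = 0.0011, adjusted p = 0.645 with an estimated correlation). So were dendritic and Langerhans cell genes (14 tested, camera adjusted p = 3.0e-04, adjusted p = 0.645 with an estimated correlation) and adipocyte genes (14 tested, camera adjusted p = 1.2e-04, adjusted p = 0.645 with an estimated correlation). Over all genes tested 0 members rose and 0 fell in each of these lists. Counts adjusted over the list alone were 2 higher and 0 lower for periodontal ligament and tendon genes, 0 higher and 1 lower for dendritic and Langerhans cell genes and 0 higher and 1 lower for adipocyte genes, and 0 for the other lists named. Tra 3, with 62.9% of its counts in 10 genes, had neutrophil and precursor scores of -2.24 and -1.90, against -0.16 to 0.42 and 0.27 to 0.58 in the other Tra libraries, and the adjusted p of these lists was 0.0056 and 0.0061 without it. Calls of the Schwann cell, cartilage, collagen, mitochondrially encoded and osteoblast lists were lost without 1 library. The cell cycle list changed direction without Tra 3 (adjusted p = 0.201).

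LiTra against Co asked what ligature and overload together changed in bone. Saa3 reached 750.1 ± 372 CPM (8.48 ± 0.65, adjusted p = 1.8e-05), and Mmp3 (7.50 ± 0.80), Il6 (5.99 ± 0.92) and Prnd (6.82 ± 1.71) rose as well. Sprr2a3 (8.61 ± 2.32), Sprr2a2 (6.52 ± 2.07) and Sprr2a1 (6.49 ± 2.07), cornified envelope genes, were called too. These near-identical copies can share reads, so their separate values are uncertain. Ctsk rose to 3939 ± 760.4 CPM (1.79 ± 0.30, adjusted p = 0.0012), Tnfsf11 to 31.2 ± 7.82 CPM (1.64 ± 0.28, adjusted p = 0.0016), and Acp5, the osteoclast acid phosphatase, by 1.15 ± 0.30 (adjusted p = 0.017). Il1b (3.89 ± 0.66), Mmp13 (2.36 ± 0.31) and Tnfrsf11b (0.81 ± 0.26) rose, and Bglap, which encodes osteocalcin of the bone matrix, fell (-1.12 ± 0.31, adjusted p = 0.025). Among the genes that fell, the largest decreases were in Cacna1i (-4.11 ± 0.74), Pklr (-4.11 ± 0.84), Fcer2a (-4.04 ± 0.69), Fcmr (-3.76 ± 0.63), Slc38a5 (-3.65 ± 0.55) and Cr2 (-3.58 ± 0.66); Pklr encodes the pyruvate kinase of red cells, and Fcer2a, Fcmr and Cr2 encode B cell receptors. Tnf (-0.29 ± 0.36), S100a8 (-1.26 ± 0.52), Postn (0.43 ± 0.39), Col1a1 (-0.02 ± 0.37) and Sost (-0.79 ± 0.53) did not pass.

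Osteoclast, matrix and cytokine lists ranked higher in LiTra bone. Of 19 osteoclast genes, 15 rose, 1 fell and 3 did not pass, and 17 were higher and 1 lower adjusted over the list alone. Osteoclast genes ranked higher (camera adjusted p = 5.6e-11, adjusted p = 0.343 with an estimated correlation). Of 18 genes of osteoclastogenic signals, 9 rose, 0 fell and 9 did not pass, and 10 were higher and 3 lower adjusted over the list alone. Genes of osteoclastogenic signals ranked higher (camera adjusted p = 3.4e-04, adjusted p = 0.343 with an estimated correlation). Of 19 collagen and matrix assembly genes, 10 rose, 0 fell and 9 did not pass, and 11 were higher and 0 lower adjusted over the list alone. Collagen and matrix assembly genes ranked higher (camera adjusted p = 2.4e-06, adjusted p = 0.396 with an estimated correlation). Of 19 chemokine genes, 10 rose, 1 fell and 8 did not pass, and 12 were higher and 2 lower adjusted over the list alone. Chemokine genes ranked higher (camera adjusted p = 1.9e-04, adjusted p = 0.343 with an estimated correlation). Of 19 cytokine and receptor genes, 7 rose, 1 fell and 11 did not pass, and 7 were higher and 2 lower adjusted over the list alone. Cytokine and receptor genes ranked higher (camera adjusted p = 1.8e-04, adjusted p = 0.343 with an estimated correlation).

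Blood cell lists ranked lower, beside the haemoglobin share of 0.203 to 0.525% in the LiTra libraries. Of 15 erythroid genes, 0 rose, 14 fell and 1 did not pass, and 0 were higher and 14 lower adjusted over the list alone. Erythroid genes ranked lower (camera adjusted p = 2.9e-13, adjusted p = 0.343 with an estimated correlation), with Hbb-bt at -3.02 ± 0.46, Hbb-bs at -2.99 ± 0.46, Hba-a1 at -3.01 ± 0.47 and Gata1 at -2.32 ± 0.36. Of 22 B and plasma cell genes, 2 rose, 13 fell and 7 did not pass, and 2 were higher and 14 lower adjusted over the list alone. B and plasma cell genes ranked lower (camera adjusted p = 7.2e-06, adjusted p = 0.343 with an estimated correlation), with Mzb1 at -2.31 ± 0.35. Of 22 T and NK cell genes, 0 rose, 9 fell and 13 did not pass, and 0 were higher and 11 lower adjusted over the list alone. T and NK cell genes ranked lower (camera adjusted p = 1.5e-04, adjusted p = 0.343 with an estimated correlation), with Lck at -2.17 ± 0.37. Of 13 marrow neutrophil precursor genes, 0 rose, 6 fell and 7 did not pass, and 0 were higher and 10 lower adjusted over the list alone. Marrow neutrophil precursor genes ranked lower (camera adjusted p = 7.4e-06, adjusted p = 0.47 with an estimated correlation), with Chil3 at -1.78 ± 0.44. Of 20 cell cycle genes, 0 rose, 7 fell and 13 did not pass, and 0 were higher and 11 lower adjusted over the list alone. The proliferation genes of this list ranked lower (camera adjusted p = 7.2e-06, adjusted p = 0.608 with an estimated correlation), with Mki67 at -1.3 ± 0.29. Calls of the endothelium, mechanical load and periodontal ligament lists were lost without 1 library.

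In all, 3589 of 21205 genes changed between LiTra and Co bone, 1757 higher and 1832 lower (edgeR, lowest adjusted p = 9.6e-06). The count was 2169 without Co 4, 2237 without LiTra 2 and 12 with library totals as the only scaling, under which Saa3, Mmp3 and Il6 were the named genes still called. Tnfrsf11b lost its call in 11 of 16 fits that left out 1 library, Sprr2a2 and Sprr2a1 in 10 each, Bglap in 6, Sprr2a3 in 4 and Acp5 in 2.

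LiTra against Li asked what overload added to the ligature in bone, which is the question of the series title. Ctsk was at 3300.0 ± 569.5 CPM in Li and 3939 ± 760.4 in LiTra (0.26 ± 0.29), Acp5 at 1949 ± 303 and 2134 ± 473 (0.13 ± 0.29), and Tnfsf11 at 28.2 ± 7.71 and 31.2 ± 7.82 (0.15 ± 0.28). Il1b (1.55 ± 0.60), Il6 (1.19 ± 0.74) and Mmp13 (0.39 ± 0.30) were measured with positive log2 differences, and none of the 6 passed (adjusted p 0.71 to 0.967). No gene was called by edgeR (0 of 21205, with 1352 at an unadjusted p under 0.05 and a lowest adjusted p of 0.358), 106 by DESeq2 (13 higher, 93 lower) and 1 by limma-voom, and edgeR called 2 without Tra 3.

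Erythroid genes had a median log2 difference of -1.80 between LiTra and Li. The mean erythroid score per library was 1.09 ± 0.44 in Co, -0.11 ± 0.68 in Li, 0.86 ± 0.72 in Tra and -1.83 ± 0.74 in LiTra (log2 scale, SD, n = 4). Lists ranked higher in this comparison included cytokine and receptor genes (19 tested, camera adjusted p = 5.4e-04, adjusted p = 0.572 with an estimated correlation) and mitochondrially encoded genes (13 tested, camera adjusted p = 5.4e-04, adjusted p = 0.893 with an estimated correlation). Ranked lower were erythroid genes (15 tested, camera adjusted p = 6.7e-22, adjusted p = 0.302 with an estimated correlation) and B and plasma cell genes (22 tested, camera adjusted p = 4.9e-07, adjusted p = 0.302 with an estimated correlation). So were marrow neutrophil precursor genes (13 tested, camera adjusted p = 1.4e-06, adjusted p = 0.679 with an estimated correlation) and cell cycle genes (20 tested, camera adjusted p = 3.2e-09, adjusted p = 0.679 with an estimated correlation). So were interferon response genes (20 tested, camera adjusted p = 7.7e-08, adjusted p = 0.572 with an estimated correlation). Over all genes tested 0 members rose and 0 fell in each of these lists. Counts adjusted over the list alone were 1 higher and 0 lower for cytokine and receptor genes, 0 higher and 14 lower for erythroid genes, 0 higher and 5 lower for B and plasma cell genes and 0 higher and 1 lower for interferon response genes, and 0 for the other lists named. Gata1 (-1.55 ± 0.35), Ighm (-2.57 ± 0.44), Mzb1 (-1.90 ± 0.34) and Rsad2 (-1.37 ± 0.36) are members of the lower lists. The calls of the osteoclastogenic signal and T and NK cell lists were lost without 1 library.

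Whether the ligature acted differently on bone with and without overload was tested as an interaction. No gene was called by edgeR (0 of 21205, with 644 at an unadjusted p under 0.05 and a lowest adjusted p near 1), 8 by DESeq2 and 0 by limma-voom. The ligature difference of the erythroid list was more negative with overload by a median log2 of -1.67. Lists ranked higher in this comparison included cytokine and receptor genes (19 tested, camera adjusted p = 2.4e-04, adjusted p = 0.573 with an estimated correlation). Ranked lower were erythroid genes (15 tested, camera adjusted p = 8.2e-15, adjusted p = 0.573 with an estimated correlation) and interferon response genes (20 tested, camera adjusted p = 1.3e-09, adjusted p = 0.573 with an estimated correlation). So were skeletal muscle genes (20 tested, camera adjusted p = 1.2e-07, adjusted p = 0.709 with an estimated correlation). Over all genes tested 0 members rose and 0 fell in each of these lists. Counts adjusted over the list alone were 1 higher and 0 lower for cytokine and receptor genes and 0 higher and 13 lower for erythroid genes, and 0 for the other lists named.

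LiTra against Tra asked what the ligature changed in overloaded bone. Saa3 (9.13 ± 0.67), Mmp3 (7.42 ± 0.80), Il6 (6.43 ± 0.94), Il1b (4.22 ± 0.67), Ptgs2 (4.13 ± 0.67) and Ccl2 (3.62 ± 0.57) rose (adjusted p 3.0e-05 to 0.0037). Ctsk (1.47 ± 0.29), Acp5 (1.18 ± 0.30), Tnfsf11 (1.15 ± 0.28) and Mmp13 (1.89 ± 0.31) rose, and Bglap fell (-1.36 ± 0.32). Decreases were largest in Pklr (-3.75 ± 0.83), Slc38a5 (-3.51 ± 0.55), Apol11b (-3.37 ± 0.63), Cldn13 (-3.19 ± 0.56), Samd11 (-3.19 ± 0.57) and Pkhd1l1 (-3.10 ± 0.43). Sost (-1.58 ± 0.54) and Tnfrsf11b (0.17 ± 0.26) did not pass.

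Osteoclast and cytokine lists ranked higher here too. Of 19 osteoclast genes, 15 rose, 1 fell and 3 did not pass, and 16 were higher and 1 lower adjusted over the list alone. Osteoclast genes ranked higher (camera adjusted p = 1.0e-16, adjusted p = 0.169 with an estimated correlation). Of 18 genes of osteoclastogenic signals, 9 rose, 0 fell and 9 did not pass, and 11 were higher and 2 lower adjusted over the list alone. Genes of osteoclastogenic signals ranked higher (camera adjusted p = 4.4e-06, adjusted p = 0.169 with an estimated correlation). Of 19 cytokine and receptor genes, 7 rose, 0 fell and 12 did not pass, and 8 were higher and 0 lower adjusted over the list alone. Cytokine and receptor genes ranked higher (camera adjusted p = 3.0e-08, adjusted p = 0.169 with an estimated correlation). Of 15 erythroid genes, 0 rose, 14 fell and 1 did not pass, and 0 were higher and 14 lower adjusted over the list alone. Erythroid genes ranked lower (camera adjusted p = 1.6e-17, adjusted p = 0.169 with an estimated correlation), with Alas2 at -3.01 ± 0.50. Of 22 B and plasma cell genes, 2 rose, 6 fell and 14 did not pass, and 2 were higher and 14 lower adjusted over the list alone. B and plasma cell genes ranked lower (camera adjusted p = 5.4e-05, adjusted p = 0.235 with an estimated correlation). Of 20 interferon response genes, 0 rose, 2 fell and 18 did not pass, and 0 were higher and 2 lower adjusted over the list alone. Interferon response genes ranked lower (camera adjusted p = 5.2e-04, adjusted p = 0.52 with an estimated correlation), with Rsad2 at -2.44 ± 0.37 and Isg15 at -1.57 ± 0.33. Camera called 18 of the 34 lists in this comparison, and 0 with an estimated correlation.

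Between LiTra and Tra bone 1179 of 21205 genes changed, 652 higher and 527 lower (edgeR, lowest adjusted p = 3.0e-05). The count was 697 without Tra 2, 1956 without Tra 3, 617 without Tra 4, 536 without LiTra 2, 708 without LiTra 3, 617 without LiTra 4, 438 in a fit of these groups alone, 2250 without Co 3, Tra 3 and LiTra 1 together and 5 with library totals as the only scaling. Acp5, Bglap and Tnfsf11 lost their calls in 5, 4 and 3 of 16 fits that left out 1 library.

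**Figure D1:**
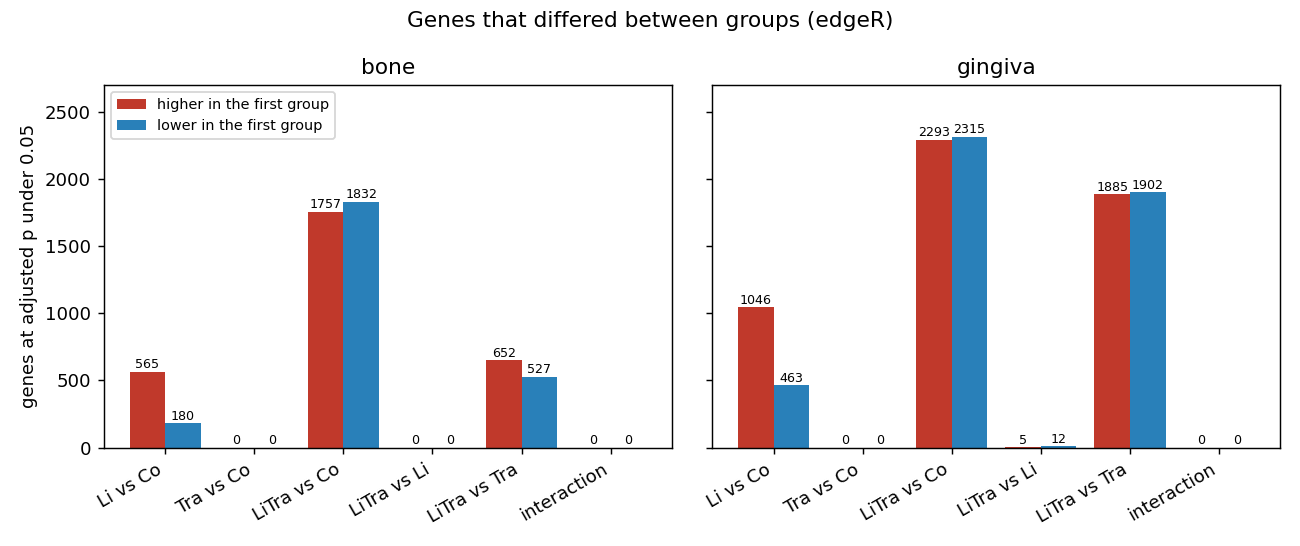
Number of genes higher (left bar of each pair) and lower (right bar) in the first group of each comparison in bone and gingiva. Genes were called at an adjusted p under 0.05 in edgeR, with 4 libraries per group. Counts were 745 and 1509 for Li against Co in bone and gingiva, 3589 and 4608 for LiTra against Co, and 0 for Tra against Co in both tissues.

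In gingiva, Li against Co asked what the ligature changed in the soft tissue. Saa3 rose from 1.17 ± 1.03 to 577 ± 556 CPM (8.94 ± 1.28, adjusted p = 0.0019), and Mmp3 from 3.41 ± 0.119 to 264 ± 279 CPM (6.27 ± 1.01). Il19 and Il17f, cytokine genes, had 0 counts in all 4 Co libraries and were at least 195-fold and 167-fold higher in Li against 3 counts over the Co group (adjusted p = 0.0094 and 0.045). Il6 (7.37 ± 1.60) and Sprr2b (6.35 ± 1.3), a small proline-rich protein of the epithelial envelope, rose. The Li libraries were far apart: Il6 was at 20.6 and 25.2 CPM in Li 1 and Li 2 and at 0.244 and 0.533 in Li 3 and Li 4, and S100a8 at 2861 and 2268 CPM against 424 and 357. Osteoclast genes rose in this tissue as well, with Acp5 at 2.28 ± 0.37 and Ctsk at 2.04 ± 0.39, and so did Tnfsf11 (4.17 ± 0.74), Mmp13 (3.88 ± 0.52) and the neutrophil calprotectin gene S100a8 (3.18 ± 0.76). The largest decreases were in Lypd2 (-2.32 ± 0.55), Bglap (-2.21 ± 0.61), Bglap2 (-2.21 ± 0.59), Krt1 (-2.1 ± 0.41), Adcy8 (-2.07 ± 0.58) and Wnt10b (-2.01 ± 0.39); Bglap and Bglap2 share reads, so the separate values are uncertain. Il1b (2.25 ± 0.84), Tnf (0.56 ± 0.43), Tnfrsf11b (0.46 ± 0.32), Postn (-0.39 ± 0.24) and Col1a1 (0.19 ± 0.44) did not pass.

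Osteoclast, leukocyte and cytokine lists ranked higher in Li gingiva. Of 19 osteoclast genes, 15 rose, 0 fell and 4 did not pass, and 19 were higher and 0 lower adjusted over the list alone. Osteoclast genes ranked higher (camera adjusted p = 1.0e-16, adjusted p = 0.296 with an estimated correlation), with Slc9b2 at 2.75 ± 0.39, Itgb3 at 1.98 ± 0.28 and Ocstamp at 3.82 ± 0.59. Of 18 genes of osteoclastogenic signals, 5 rose, 0 fell and 13 did not pass, and 10 were higher and 0 lower adjusted over the list alone. Genes of osteoclastogenic signals ranked higher (camera adjusted p = 2.7e-05, adjusted p = 0.423 with an estimated correlation). Of 18 monocyte and macrophage genes, 10 rose, 0 fell and 8 did not pass, and 17 were higher and 0 lower adjusted over the list alone. Monocyte and macrophage genes ranked higher (camera adjusted p = 1.9e-10, adjusted p = 0.296 with an estimated correlation), with Csf1r at 1.86 ± 0.25 and Cd68 at 1.98 ± 0.34. Of 18 neutrophil genes, 3 rose, 0 fell and 15 did not pass, and 13 were higher and 0 lower adjusted over the list alone. Neutrophil genes ranked higher (camera adjusted p = 6.3e-06, adjusted p = 0.45 with an estimated correlation). Of 20 chemokine genes, 9 rose, 0 fell and 11 did not pass, and 15 were higher and 0 lower adjusted over the list alone. Chemokine genes ranked higher (camera adjusted p = 2.4e-06, adjusted p = 0.365 with an estimated correlation), with Ccl9 at 3.46 ± 0.57. Of 20 cytokine and receptor genes, 6 rose, 0 fell and 14 did not pass, and 9 were higher and 0 lower adjusted over the list alone. Cytokine and receptor genes ranked higher (camera adjusted p = 9.8e-06, adjusted p = 0.358 with an estimated correlation), with Il1rl1 at 3.55 ± 0.49.

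Vessel, matrix and cell cycle lists were higher as well. Of 17 endothelial genes, 11 rose, 0 fell and 6 did not pass, and 14 were higher and 0 lower adjusted over the list alone. Endothelial genes ranked higher (camera adjusted p = 8.1e-12, adjusted p = 0.296 with an estimated correlation), with Pecam1 at 1.25 ± 0.17. Of 19 collagen and matrix assembly genes, 11 rose, 0 fell and 8 did not pass, and 18 were higher and 0 lower adjusted over the list alone. Collagen and matrix assembly genes ranked higher (camera adjusted p = 2.2e-11, adjusted p = 0.296 with an estimated correlation). Of 16 metalloproteinase and inhibitor genes, 7 rose, 1 fell and 8 did not pass, and 11 were higher and 2 lower adjusted over the list alone. Metalloproteinase and inhibitor genes ranked higher (camera adjusted p = 3.0e-05, adjusted p = 0.358 with an estimated correlation). Of 20 cell cycle genes, 3 rose, 0 fell and 17 did not pass, and 7 were higher and 0 lower adjusted over the list alone. The proliferation genes of this list ranked higher (camera adjusted p = 1.8e-05, adjusted p = 0.45 with an estimated correlation), with Birc5 at 0.79 ± 0.16. Of 18 hypoxia and glycolysis genes, 5 rose, 0 fell and 13 did not pass, and 11 were higher and 0 lower adjusted over the list alone. Hypoxia and glycolysis genes ranked higher (camera adjusted p = 1.9e-05, adjusted p = 0.296 with an estimated correlation).

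Bone matrix and epithelial barrier lists ranked lower. Of 18 osteoblast and bone matrix genes, 1 rose, 3 fell and 14 did not pass, and 1 was higher and 8 lower adjusted over the list alone. Osteoblast and bone matrix genes ranked lower (camera adjusted p = 0.0026, adjusted p = 0.45 with an estimated correlation). Spp1, which encodes osteopontin, was the member that rose (3.32 ± 0.76). Of 19 cornified envelope genes, 1 rose, 1 fell and 17 did not pass, and 1 was higher and 1 lower adjusted over the list alone. Cornified envelope genes ranked lower (camera adjusted p = 1.1e-04, adjusted p = 0.45 with an estimated correlation). Of 22 Wnt and BMP genes, 2 rose, 2 fell and 18 did not pass, and 2 were higher and 4 lower adjusted over the list alone. Wnt and BMP genes ranked lower (camera adjusted p = 0.001, adjusted p = 0.358 with an estimated correlation). Wnt10b was a member that fell, while Sfrp1, which encodes a secreted Wnt inhibitor, rose (1.41 ± 0.25). The calls of the Schwann cell, antimicrobial and marrow neutrophil precursor lists were lost without 1 library, and that of mitochondrially encoded genes with each library's trend on GC content removed.

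Of 20143 genes tested in gingiva 1509 changed between Li and Co, 1046 higher and 463 lower (edgeR, lowest adjusted p = 0.00032). The count was 521 without Co 1, 700 without Co 3, 721 without Co 4, 695 without Li 1, 540 without Li 2 and 407 in a fit of these groups alone. Adcy8, Il17f, Bglap, Bglap2, S100a8, Lypd2 and Il6 lost their calls in 13, 12, 8, 5, 5, 3 and 1 of 16 fits that left out 1 library, and Il19, Il17f, Saa3, Il6, Sprr2b, Mmp3, Tnfsf11 and S100a8 were not called by limma-voom.

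Tra against Co in gingiva asked what overload alone changed there. Acp5 was at 42.7 ± 7.33 CPM in Co and 62.8 ± 48.5 in Tra (0.56 ± 0.36), Ctsk at 96.6 ± 16.1 and 137 ± 107 (0.50 ± 0.38), and Tnfsf11 at 0.602 ± 0.396 and 1.84 ± 1.3 (1.62 ± 0.69). Mmp13 (0.59 ± 0.47) and Il6 (-0.72 ± 2.19) were measured likewise, and none of these passed (adjusted p 0.713 to 0.994). No gene was called by edgeR (0 of 20143, with 1323 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0583), 92 by DESeq2 and 4 by limma-voom, and edgeR called 2 without Li 2 and 3 without Li 4. Of 19 collagen and matrix assembly genes, 0 rose, 0 fell and 19 did not pass, and 2 were higher and 0 lower adjusted over the list alone. Collagen and matrix assembly genes ranked higher (camera adjusted p = 7.5e-06, adjusted p = 0.995 with an estimated correlation). Camera calls of the monocyte, oral keratinocyte and T and NK cell lists were lost without 1 library, and the osteoclast list changed direction without Tra 2 (adjusted p = 0.821).

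LiTra against Co in gingiva asked what both treatments changed. Saa3 reached 699 ± 458 CPM (9.22 ± 1.30, adjusted p = 4.7e-04), Il19 was at least 409-fold higher against 3 counts over the Co group, and Il6 (7.62 ± 1.61), Sprr2b (7.26 ± 1.36), F10 (6.43 ± 1.35) and Mmp3 (6.26 ± 1.01) rose; F10 encodes coagulation factor X. Tnfsf11 (4.79 ± 0.75), Ctsk (2.61 ± 0.40), Acp5 (2.51 ± 0.38), Mmp13 (4.60 ± 0.54), S100a8 (3.82 ± 0.79) and Il1b (2.79 ± 0.85) rose, and Bglap fell (-3.42 ± 0.64). Where groups did not overlap, decreases were largest in Cldn2 (-7.19 ± 1.62), Azgp1 (-7.04 ± 1.71), Mylk4 (-6.73 ± 1.57), Ckmt2 (-6.62 ± 1.58), Ppp1r1b (-6.25 ± 1.40) and Ky (-6.23 ± 1.49). Mylk4, Ckmt2 and Ky are muscle genes. Tnfrsf11b (0.84 ± 0.32), Tnf (0.61 ± 0.43) and Col1a1 (-0.87 ± 0.44) did not pass.

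Osteoclast, leukocyte and cytokine lists ranked higher. Of 19 osteoclast genes, 18 rose, 0 fell and 1 did not pass, and 19 were higher and 0 lower adjusted over the list alone. Osteoclast genes ranked higher (camera adjusted p = 1.6e-13, adjusted p = 0.334 with an estimated correlation). Of 18 genes of osteoclastogenic signals, 10 rose, 0 fell and 8 did not pass, and 12 were higher and 0 lower adjusted over the list alone. Genes of osteoclastogenic signals ranked higher (camera adjusted p = 7.4e-05, adjusted p = 0.344 with an estimated correlation). Of 18 neutrophil genes, 10 rose, 0 fell and 8 did not pass, and 16 were higher and 0 lower adjusted over the list alone. Neutrophil genes ranked higher (camera adjusted p = 3.2e-07, adjusted p = 0.352 with an estimated correlation). Of 18 monocyte and macrophage genes, 13 rose, 0 fell and 5 did not pass, and 15 were higher and 0 lower adjusted over the list alone. Monocyte and macrophage genes ranked higher (camera adjusted p = 2.1e-08, adjusted p = 0.334 with an estimated correlation). Of 20 cytokine and receptor genes, 8 rose, 2 fell and 10 did not pass, and 12 were higher and 2 lower adjusted over the list alone. Cytokine and receptor genes ranked higher (camera adjusted p = 1.9e-05, adjusted p = 0.334 with an estimated correlation).

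Cell cycle, vessel and matrix lists ranked higher as well. Of 20 cell cycle genes, 15 rose, 0 fell and 5 did not pass, and 16 were higher and 0 lower adjusted over the list alone. The proliferation genes of this list ranked higher (camera adjusted p = 2.1e-08, adjusted p = 0.334 with an estimated correlation), with Birc5 at 1.19 ± 0.16 and Top2a at 1.01 ± 0.18. Of 17 endothelial genes, 11 rose, 1 fell and 5 did not pass, and 11 were higher and 1 lower adjusted over the list alone. Endothelial genes ranked higher (camera adjusted p = 2.9e-06, adjusted p = 0.334 with an estimated correlation). Of 19 collagen and matrix assembly genes, 9 rose, 0 fell and 10 did not pass, and 12 were higher and 0 lower adjusted over the list alone. Collagen and matrix assembly genes ranked higher (camera adjusted p = 3.2e-07, adjusted p = 0.334 with an estimated correlation).

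Epithelial, gland, muscle and nerve lists ranked lower. Of 19 cornified envelope genes, 1 rose, 10 fell and 8 did not pass, and 1 was higher and 13 lower adjusted over the list alone. Cornified envelope genes ranked lower (camera adjusted p = 1.0e-04, adjusted p = 0.356 with an estimated correlation), with Flg at -2.96 ± 0.73 and Tgm3 at -1.73 ± 0.29. Of 22 Wnt and BMP genes, 3 rose, 13 fell and 6 did not pass, and 3 were higher and 15 lower adjusted over the list alone. Wnt and BMP genes ranked lower (camera adjusted p = 8.2e-05, adjusted p = 0.334 with an estimated correlation), with Wnt4 at -1.02 ± 0.18 and Bmp6 at -2.86 ± 0.50. Of 18 osteoblast and bone matrix genes, 2 rose, 10 fell and 6 did not pass, and 2 were higher and 10 lower adjusted over the list alone. Osteoblast and bone matrix genes ranked lower (camera adjusted p = 0.0013, adjusted p = 0.356 with an estimated correlation), with Phospho1 at -1.89 ± 0.29. Spp1 rose in that list (4.23 ± 0.79). Of 20 skeletal muscle genes, 0 rose, 9 fell and 11 did not pass, and 0 were higher and 16 lower adjusted over the list alone. Skeletal muscle genes ranked lower (camera adjusted p = 1.6e-04, adjusted p = 0.548 with an estimated correlation), with Mb at -4.67 ± 1.15 and Tcap at -5.08 ± 1.31. Of 11 salivary and minor gland genes, 1 rose, 8 fell and 2 did not pass, and 1 was higher and 8 lower adjusted over the list alone. Salivary and minor gland genes ranked lower (camera adjusted p = 0.013, adjusted p = 0.356 with an estimated correlation), with Tff2 at -12.46 ± 2.58 and Dcpp3 at -10.69 ± 2.26. Of 11 Schwann cell and nerve genes, 0 rose, 5 fell and 6 did not pass, and 0 were higher and 7 lower adjusted over the list alone. Schwann cell and nerve genes ranked lower (camera adjusted p = 7.8e-04, adjusted p = 0.344 with an estimated correlation), with Mbp at -0.90 ± 0.16.

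Gland scores were 0.99 ± 3.42 in Co, 1.25 ± 1.21 in Li, 1.28 ± 1.70 in Tra and -3.52 ± 0.80 in LiTra, and muscle scores 0.89 ± 2.1, 0.39 ± 1.33, 0.46 ± 2.78 and -1.75 ± 0.75 (log2 scale, SD, n = 4). In gingiva 4608 of 20143 genes changed between LiTra and Co, 2293 higher and 2315 lower (edgeR, adjusted p from 1.9e-05). With the GC trend removed 4591 passed. Unmatched identifiers took 0.360 to 0.409% in Co and 0.168 to 0.183% in LiTra, so a library batch stays open. Cldn2, Azgp1, Mylk4, Ckmt2, Ppp1r1b, Ky, Il6 and Sprr2b were not called by limma-voom, Il1b lost its call in 5 of 16 fits that left out 1 library, and the dendritic cell list lost its call without Co 1.

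LiTra against Li in gingiva asked what overload added to the ligature. The genes that rose were Cep192 (0.54 ± 0.09), Npat (0.44 ± 0.07), Smc6 (0.43 ± 0.07), Fnbp1l (0.42 ± 0.07) and Tmem168 (0.36 ± 0.06); Cep192 acts in centrosome assembly, Npat in histone gene transcription and Smc6 in chromosome maintenance. The largest decreases were in Rgma (-1.33 ± 0.23), Tpcn1 (-1.24 ± 0.21), Zfp750 (-1.14 ± 0.19), Fjx1 (-1.04 ± 0.18), Zbtb7c (-0.95 ± 0.16) and Otud1 (-0.83 ± 0.14) (adjusted p = 0.045 each); Zfp750 regulates epidermal differentiation. Ctsk (0.57 ± 0.38), Acp5 (0.23 ± 0.36), Tnfsf11 (0.62 ± 0.63), Mmp13 (0.72 ± 0.47) and Col1a1 (-1.06 ± 0.44) did not pass.

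Cell cycle genes ranked higher, and muscle, gland, fat and nerve genes lower. The slope of log2 CPM, less each gene's mean over libraries, on GC content was -0.235 to -0.106 per 10 points in the LiTra gingiva libraries, -0.002 to 0.171 in Li and -0.007 to 0.086 in Co, and log2 differences between LiTra and Li correlated with GC content across genes (r = -0.31). Lists ranked higher in this comparison included cell cycle genes (20 tested, camera adjusted p = 3.7e-04, adjusted p = 0.777 with an estimated correlation). Ranked lower were skeletal muscle genes (20 tested, camera adjusted p = 3.4e-05, adjusted p = 0.777 with an estimated correlation) and salivary and minor gland genes (11 tested, camera adjusted p = 0.0013, adjusted p = 0.777 with an estimated correlation). So were adipocyte genes (14 tested, camera adjusted p = 0.0013, adjusted p = 0.777 with an estimated correlation) and Schwann cell and nerve genes (11 tested, camera adjusted p = 0.017, adjusted p = 0.777 with an estimated correlation). Over all genes tested 0 members rose and 0 fell in each of these lists. Counts adjusted over the list alone were 1 higher and 8 lower for salivary and minor gland genes, and 0 for the other lists named. The calls of the B and plasma cell, cartilage, erythroid, hypoxia, marrow neutrophil precursor and neutrophil lists were lost without 1 library. In this comparison 17 genes changed, 5 higher and 12 lower (edgeR, lowest adjusted p = 0.018), with 1413 by DESeq2 and 860 by limma-voom. The count was 893 without Li 1, 153 without Tra 2, 2 without Co 4, 1 without Co 1, Co 2, Co 3, Li 4, Tra 1 or Tra 3, and 0 without Li 2, Li 3 or any 1 of the LiTra libraries. It was 1 with no filter on low counts, 1 in a fit of these groups alone, 1 with each library's trend on GC content removed, 0 with library totals as the only scaling and 145 with a stricter filter, and the 11 named genes each lost their calls in the first 4 of these.

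For the interaction in gingiva, whether the ligature acted differently with and without overload, no gene was called by edgeR (0 of 20143, with 2289 at an unadjusted p under 0.05 and a lowest adjusted p of 0.255), 183 by DESeq2 and 0 by limma-voom, and edgeR called 1 without Co 4. Lists ranked higher in this comparison included cell cycle genes (20 tested, camera adjusted p = 6.4e-05, adjusted p = 0.88 with an estimated correlation). Ranked lower were salivary and minor gland genes (11 tested, camera adjusted p = 0.001, adjusted p = 0.88 with an estimated correlation) and adipocyte genes (14 tested, camera adjusted p = 0.001, adjusted p = 0.88 with an estimated correlation). Over all genes tested 0 members rose and 0 fell in each of these lists. Counts adjusted over the list alone were 0 higher and 7 lower for salivary and minor gland genes, and 0 for the other lists named.

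LiTra against Tra in gingiva asked what the ligature changed in overloaded tissue. Saa3 (9.74 ± 1.33), Il6 (8.34 ± 1.69), Il19 (7.65 ± 1.39), Sprr2b (6.23 ± 1.26), Il17a (5.82 ± 1.41) and Lrat (5.16 ± 0.68) rose. Mmp13 (4.01 ± 0.53), S100a8 (4.27 ± 0.80), Tnfsf11 (3.17 ± 0.69), Il1b (3.01 ± 0.86), Ctsk (2.1 ± 0.39), Acp5 (1.95 ± 0.37) and Tnfrsf11b (1.08 ± 0.33) rose, and Bglap fell (-3.07 ± 0.63). The largest decreases were in gland genes. Dcpp2 and Ern2 had 0 counts in all 4 LiTra libraries and were at least 2544-fold and 275-fold lower against 3 counts over that group. Tff2 (-11.24 ± 2.49), Dcpp3 (-9.45 ± 2.22), Bpifb2 (-9.19 ± 2.29) and Smgc (-8.92 ± 2.36) fell. The Dcpp copies can share reads, so their separate values are uncertain. Krt1 (-3.33 ± 0.44) and Krt10 (-2.67 ± 0.50), keratins of differentiated epithelium, fell, and the desmosomal gene Dsg3 rose (0.86 ± 0.16).

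Osteoclast, neutrophil and cell cycle lists ranked higher, and epithelial and muscle lists lower. Of 19 osteoclast genes, 13 rose, 0 fell and 6 did not pass, and 17 were higher and 0 lower adjusted over the list alone. Osteoclast genes ranked higher (camera adjusted p = 1.7e-13, adjusted p = 0.303 with an estimated correlation). Of 18 neutrophil genes, 14 rose, 0 fell and 4 did not pass, and 16 were higher and 0 lower adjusted over the list alone. Neutrophil genes ranked higher (camera adjusted p = 7.6e-10, adjusted p = 0.303 with an estimated correlation). Of 20 cytokine and receptor genes, 14 rose, 0 fell and 6 did not pass, and 15 were higher and 2 lower adjusted over the list alone. Cytokine and receptor genes ranked higher (camera adjusted p = 2.9e-07, adjusted p = 0.303 with an estimated correlation). Of 20 cell cycle genes, 13 rose, 0 fell and 7 did not pass, and 17 were higher and 0 lower adjusted over the list alone. The proliferation genes of this list ranked higher (camera adjusted p = 6.5e-11, adjusted p = 0.303 with an estimated correlation). Of 19 cornified envelope genes, 2 rose, 10 fell and 7 did not pass, and 2 were higher and 15 lower adjusted over the list alone. Cornified envelope genes ranked lower (camera adjusted p = 8.9e-05, adjusted p = 0.341 with an estimated correlation). Of 19 oral keratinocyte genes, 1 rose, 10 fell and 8 did not pass, and 2 were higher and 11 lower adjusted over the list alone. Oral keratinocyte genes ranked lower (camera adjusted p = 0.0069, adjusted p = 0.437 with an estimated correlation). Of 20 skeletal muscle genes, 0 rose, 9 fell and 11 did not pass, and 0 were higher and 20 lower adjusted over the list alone. Skeletal muscle genes ranked lower (camera adjusted p = 3.7e-04, adjusted p = 0.495 with an estimated correlation). Camera called 23 of the 34 lists here, and 0 with an estimated correlation.

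In all 3787 of 20143 genes changed between LiTra and Tra gingiva, 1885 higher and 1902 lower (edgeR, lowest adjusted p = 0.00032), 3100 and 1257 with library totals as the only scaling, and 2402 in all without LiTra 4. Tnfrsf11b, Il1b, Ern2 and Smgc lost their calls in 5, 4, 2 and 1 of 16 fits that left out 1 library, and Il6, Il19, Sprr2b, Il17a, Dcpp2, Tff2, Ern2, Dcpp3, Bpifb2 and Smgc were not called by limma-voom. Lists of osteocyte, nasal respiratory epithelium and tooth genes were not called by camera in any of the 6 comparisons of either tissue.

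**Figure D2:**
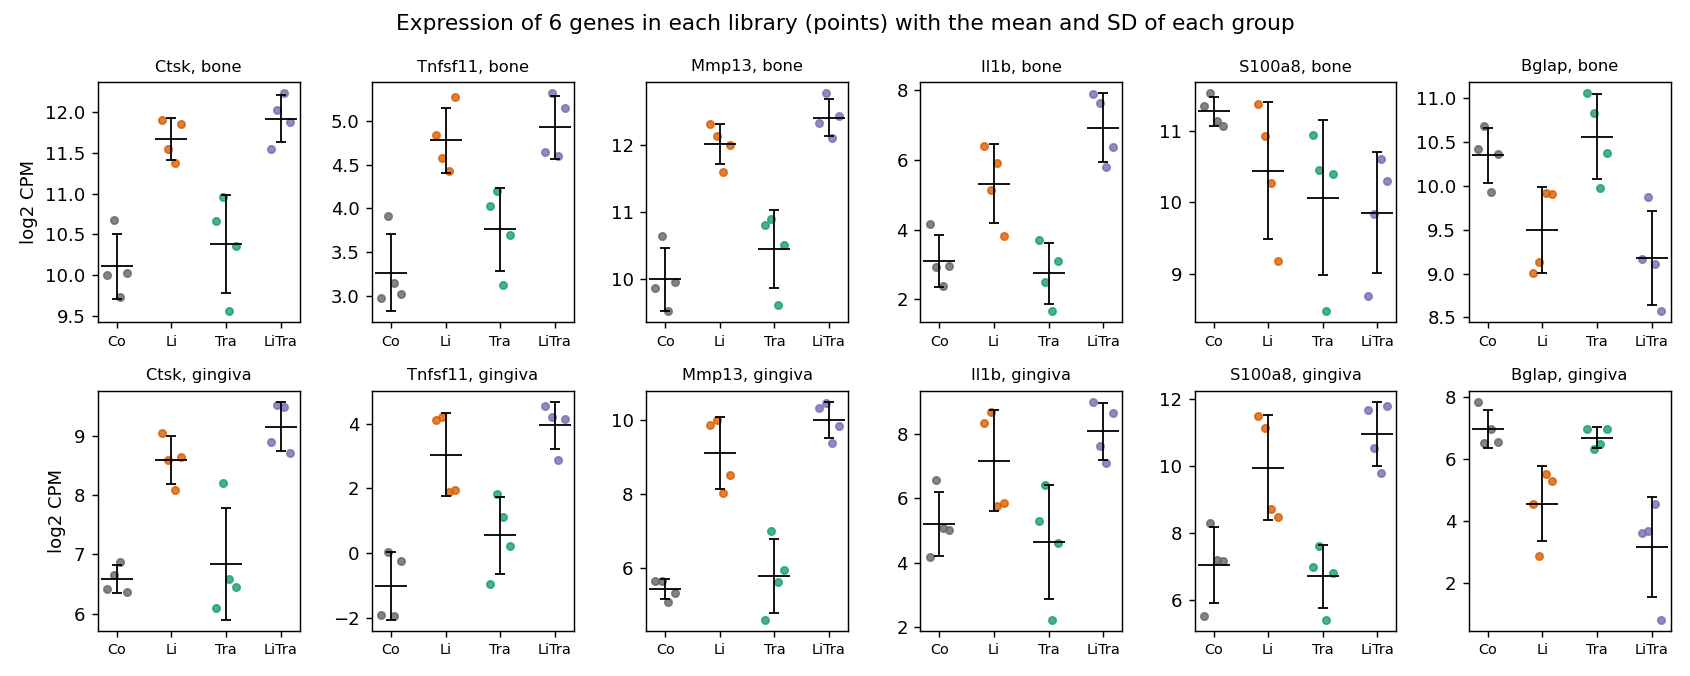
Level of Ctsk, Tnfsf11, Mmp13, Il1b, S100a8 and Bglap in log2 CPM for each library (points) with the group mean and SD (bars), by group (n = 4) and tissue. In bone Ctsk rose between Co and Li by 1.54 ± 0.29 (log2 ± SE) and between Co and LiTra by 1.79 ± 0.30.

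**Figure D3:**
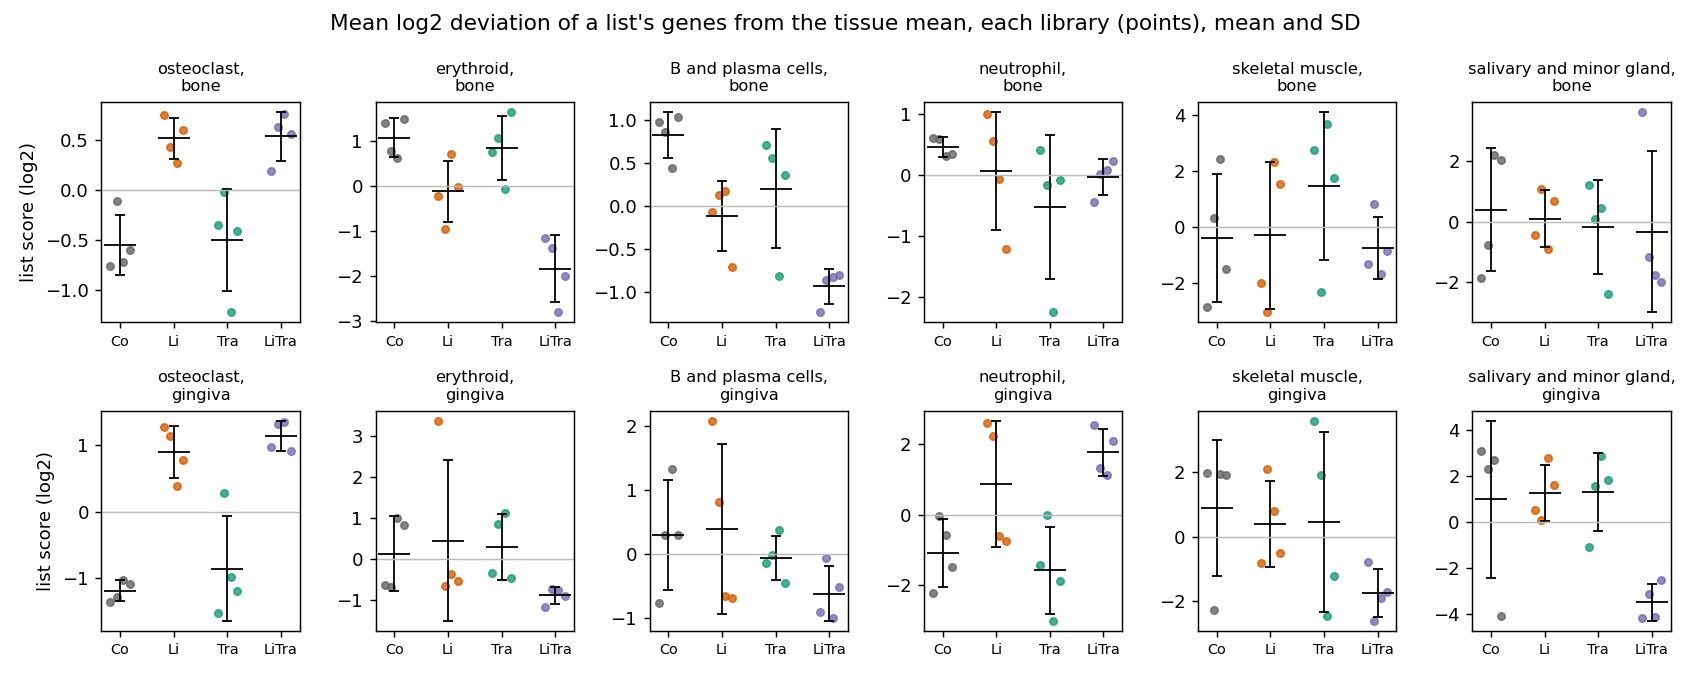
Mean list score per library (points) on a log2 scale, with the group mean and SD (bars), for the osteoclast, erythroid, B and plasma cell, neutrophil, skeletal muscle and gland lists in both tissues (n = 4 per group). The erythroid score in bone was 1.09 ± 0.44 in Co and -1.83 ± 0.74 in LiTra.

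Li against Co and LiTra against Tra share no libraries, so they estimate the ligature effect separately. In bone, of 565 and 652 genes that rose, 363 were shared (17.4 for independent lists), and of 180 and 527 that fell, 85 were shared (4.47), with 0 in opposite directions; the log2 changes correlated across 14586 genes with Pearson r = 0.53 and Spearman rho = 0.68. In gingiva 704 genes were shared among those that rose (97.9 for independent lists) and 233 among those that fell (43.7), 1 and 3 of the genes that rose and fell in Li going the other way in LiTra against Tra, with r = 0.57 and rho = 0.62 across 14265 genes. Tra against Co and LiTra against Li, the separate estimates of the overload effect, correlated across genes with r = 0.32 and rho = 0.48 in bone and r = -0.03 and rho = 0.11 in gingiva. Genes are not independent replicates, so no p is given.

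Bone and gingiva overlapped in part. Of 19225 genes tested in both tissues, 175 rose with the ligature in both (30.2 for independent lists) and 5 fell in both (4.05), while 6 rose and 3 fell in bone and went the other way in gingiva (r = 0.28, rho = 0.15 across genes). Between LiTra and Co 570 rose in both (206 for independent lists) and 274 fell in both (198), with 56 and 129 opposite (r = 0.30, rho = 0.20), and between LiTra and Tra 282 rose (63.0) and 95 fell (45.5), with 16 and 18 opposite (r = 0.47, rho = 0.29). Whether the ligature effect itself differed between the tissues was tested in 1 fit of both, where 461 of 22559 genes had a different log2 change, 307 more positive in bone and 154 more positive in gingiva (edgeR). Ostn, which encodes a secreted peptide of bone and muscle, went from 2.06 in bone to -1.23 in gingiva, and Vpreb3, a gene of developing B cells, from -1.61 to 8.21; the gingiva library Li 1 carried 0.246% haemoglobin, the highest share among the Li gingiva libraries. The count of 461 was 253 without Co 1, 204 without Co 2, 278 without Co 3, 52 without Co 4, 286 without Li 1, 63 without Li 2, 937 without Tra 3 and 276 without LiTra 2, each left out of both tissues, and 1354 (566 more positive in bone, 788 in gingiva) without the 3 bone libraries rich in nasal gland transcripts. No gene differed between the tissues for Tra against Co (0, with 1456 at an unadjusted p under 0.05, 61 by DESeq2, and edgeR 2 without Co 1) or LiTra against Li (0, with 1869 at an unadjusted p under 0.05, 96 by DESeq2, and edgeR 1 without LiTra 3).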

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

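The tests of the marrow share and of GC content, and the fit without Co 3, Tra 3 and LiTra 1, were chosen only after the results were seen.

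Single libraries stood far from the other 3 of their group in 14 of 148 groups of 4 values tested, where chance gives about 1 in 20, or 7.4. The gap to the nearest library as a share of the group's range is given for each. In bone, Co 2 had the largest total (70793037 counts against 42662599 to 46047069, 0.883) and the highest Acp5 (0.841) and Tnfsf11 (15.1 CPM, 0.854) of its group. Il6 was highest in Co 3 (0.666 CPM, 0.830) and in Li 1 (16.1 CPM against 5.36 to 5.84, 0.956). Tra 3 had the highest share of counts in 10 genes (62.9%, 0.932) and the most positive slope on GC content (0.979), and Tra 4 the highest Tnf (3.57 CPM, 0.839). LiTra 1 had the highest share in 10 genes (53.6%, 0.993) and the lowest mitochondrial share (1.72% against 2.90 to 3.11, 0.844). In gingiva, Li 1 had the highest haemoglobin share (0.246%, 0.848), Tra 2 the highest Acp5 (135 CPM, 0.851) and Ctsk (297 CPM against 68.1 to 95.9, 0.878), and Tra 4 was the library of its group with Il6 above 0 (0.165 CPM, 1).

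The ligature effect differed between the tissues for 461 genes. Bone minus gingiva log2 was 3.29 (Ostn), 2.94 (Mt3), 2.92 (Akr1c18) and 2.59 (Cpa6), and -9.81 (Vpreb3), -8.25 (Mcpt8), -7.89 (Mzb1) and -6.99 (Prss46). The last 4 were higher in Li gingiva, where marrow precursor scores ran from -1.36 to 5.25, so uneven marrow stays open. Only the real grouping of 35 gave as many genes (highest other 38), the smallest share possible, so chance is less likely but not excluded. Tra against Co and LiTra against Li gave 0 genes, matched by 35 of 35 groupings as any count matches 0 (highest other 4 and 0), so nothing follows about chance. In the interaction camera called 11 lists in each tissue, and 0 with an estimated correlation. The gene counts of the interaction, 0 in both tissues, are matched by 100 of 100 drawn groupings for the same reason, with highest others of 2364 in bone and 3131 in gingiva; these groupings mix the 4 groups, so the ligature effect enters them.

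Bone of LiTra mice had lower erythroid, B cell and marrow precursor genes. The tables argue against counts concentrated in a few genes, since without Co 3, Tra 3 and LiTra 1 the median log2 difference of erythroid genes between LiTra and Li was -2.07, against -1.80 with them. A lower share of marrow in these samples, with all marrow lineages alike, stays open: the erythroid minus marrow precursor score was 0.22 ± 0.56 in Co and -1.02 ± 1.47 in LiTra (SD, n = 4), with an exact two-sided permutation p of 0.2. A change in erythroid and B cell genes with the treatment is the biological alternative, which cannot be told apart from a lower marrow share because the spread within LiTra is as large as the difference.

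In gingiva 17 genes differed between LiTra and Li. Less muscle and gland tissue stays open: gland scores of Li and LiTra did not overlap, so a fit cannot tell score from group. With both scores fitted the median log2 difference was 104% as large (0.76 to 0.80, median SE 0.13 to 0.20), with 0 called. GC content stays open. With each library's GC trend removed the median was 81.2% of its value (0.76 to 0.62, median SE 0.13 to 0.12) and 1 of the 17 was called, while the median GC content was 40.4% for genes that rose, 55.8% for genes that fell and 49.6% for all tested; a margin for the spread over genes (SE 3.55) was added after that value was seen, and without it 81.2% lies past the bound written for exclusion. A biological effect of overload was not separated from it, and 3 of 35 groupings gave as many genes (highest other 125, with Li 1, Li 2, LiTra 1 and LiTra 4 set against the rest), so chance is not excluded and that grouping points to structure among the samples.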

How the results depend on the processing

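The fits without 3 bone libraries and with the GC trend removed were chosen after seeing the data, and the tests by other groupings were planned. All values are numbers of genes called, main value first where given, and the cause of a change was not tested unless stated.

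In bone the real grouping was the only 1 of 35 to give as many genes for Li against Co (745, highest other 1). The same held for LiTra against Co (3589, highest other 0) and LiTra against Tra (1179, highest other 3). In gingiva it held for the same comparisons (1509, 4608 and 3787, highest others 23, 1 and 1). In each case 1 of 35 is the smallest share this test can give, so chance is less likely but not excluded. For Tra against Co the 0 genes were matched by 35 of 35 groupings in bone (highest other 3) and 35 of 35 in gingiva (highest other 47), and for LiTra against Li in bone by 35 of 35 (highest other 0), as any count matches 0, so nothing follows about chance.

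For Li against Co in bone the count was 224 at a fold change of at least 2, 189 at an adjusted p under 0.01, 5 with library totals (5 higher and 0 lower, median of all genes at 0.13), 410 with no filter, 1904 by DESeq2, 1827 by limma-voom, 398 with these groups alone (fewer samples) and 1775 without the 3 libraries. For LiTra against Co it was 1305, 1614 and 12 (12 higher, 0 lower) under the first 3 of these and 6874 by limma-voom, and for LiTra against Tra 504, 390, 5 (5 higher, 0 lower), 729, 2397, 3514, 438 and 2250 in the order given for Li. DESeq2 called 160 for Tra against Co, 106 for LiTra against Li, where limma-voom called 1, and 8 for the interaction. With library totals the median of all genes for LiTra against Li was -0.10.

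In gingiva Li against Co gave 641 at a fold change of at least 2, 337 at an adjusted p under 0.01, 921 with no filter, 2755 by DESeq2 and 407 with these groups alone. LiTra against Co gave 1884 and 2052, and LiTra against Tra 1680 and 1485, under the first 2 of these. With library totals their splits were 2898 higher and 1754 lower (main 2293 and 2315) and 3100 and 1257 (main 1885 and 1902, median of all genes at 0.13). Tra against Co gave 2 with DESeq2's size factors, 2 with the stricter filter, 92 by DESeq2 and 4 by limma-voom, and the interaction 183 by DESeq2. LiTra against Li (17) gave 5 at a fold change of at least 2, 0 at an adjusted p under 0.01, 0 with library totals, 1 with no filter, 145 with the stricter filter, 1413 by DESeq2 (495 higher, 918 lower), 860 by limma-voom (362 and 498), 1 with the GC trend removed and 1 with these groups alone. For tissue differences of Li against Co (461) there were 171 with no filter, 1488 by DESeq2 and 1354 without the 3 libraries; DESeq2 gave 61 for Tra against Co and 96 for LiTra against Li.

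Leaving out 1 library at a time gave 202 to 1232 for Li against Co, 0 to 1 for Tra against Co, 2169 to 4828 for LiTra against Co, 0 to 2 for LiTra against Li, 536 to 1956 for LiTra against Tra and 0 to 0 for the interaction in bone. In gingiva these were 521 to 2191, 0 to 3, 3206 to 4903, 0 to 893, 2402 to 4150 and 0 to 1, and for tissue differences 52 to 937 for Li against Co, 0 to 2 for Tra against Co and 0 to 1 for LiTra against Li. Over the same fits the adjusted p of the cell cycle list in bone, Tra against Co, was 0.00018 to 0.201, and it changed direction without Tra 3 (0.201). That of the osteoclast list in gingiva, Tra against Co, was 1.2e-05 to 0.821, and it changed direction without Tra 2 (0.821).

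Libraries of the same number were not treated as pairs, since deviations from the group means of same-numbered libraries correlated with a median of -0.08 in bone (5 of 24 pairs over 0.1) and 0.01 in gingiva (4 of 24), and of same-named bone and gingiva libraries with 0.04 (3 of 16). With the number as a block 585, 3185 and 936 genes were called in bone and 1320, 4601 and 3714 in gingiva for Li against Co, LiTra against Co and LiTra against Tra, 8 in gingiva for LiTra against Li, and 413 for tissue differences of Li against Co with the same-named bone and gingiva libraries as a block. The effect of depth was not tested, and in Co 3, Tra 3 and LiTra 1 bone 10 genes took 51.1%, 62.9% and 53.6% of the counts; 2-fold changes were recovered for 28% of simulated genes in bone, Li against Co, at this number of libraries.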

Other observations

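The lists of heat shock, circadian clock and nasal gland genes, and the clock index and the tests that use it or a library batch, were chosen only after the results were seen.

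Some heat shock and chaperone genes differed in bone. Of 15 tested, 5 rose and 0 fell between Li and Co, 7 and 0 between LiTra and Co and 3 and 0 between LiTra and Tra; the list had no set test. Hspa8 and Dnaja1 had log2 changes of 0.78 ± 0.13 and 0.52 ± 0.08 in Li, and 0.95 ± 0.13 and 0.72 ± 0.08 in LiTra (edgeR, SE, 4 libraries per group). Between Tra and Co 0 rose and 0 fell, with Hspa8 at 0.61 ± 0.13 and Dnaja1 at 0.41 ± 0.08, and the list's median was 0.35 there, against 0.43 between Li and Co and 0.15 between LiTra and Tra. In gingiva 1 of 15 rose between Li and Co, which was Hspa8 (0.68 ± 0.09), and 5 rose and 2 fell between LiTra and Co.

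Some circadian clock genes differed too, in a list with no set test; 0 of 17 were called between Tra and Co or LiTra and Li in either tissue. In gingiva 1 of 17 rose and 6 fell between Li and Co, and 2 rose and 9 fell between LiTra and Co. Nr1d1 and Dbp, clock output genes that peak by day in mice, fell by 1.40 and 1.36 on the log2 scale in Li gingiva and by 1.92 and 1.89 in LiTra, and Nfil3, which acts against Dbp, rose by 2.04 ± 0.34 and 1.82 ± 0.34. In bone 1 rose and 2 fell between Li and Co, with Nr1d1 at -1.66 ± 0.32 and Dbp at -1.60 ± 0.34. An index of clock phase, computed as the mean log2 CPM of Arntl, Npas2 and Clock minus that of 9 genes of the opposite phase, was higher than in Co by 1.30 in Li, 0.92 in Tra and 1.04 in LiTra bone, and by 1.14, 0.89 and 1.40 in gingiva. No p is given, since the index was built from genes seen to differ. The Tra libraries were far apart: in Tra 1 to 4 it was -2.99, -2.77, -1.52 and -1.03 in bone and -2.69, -2.27, -1.17 and -1.31 in gingiva, beside Co means of -3.00 and -2.76. In Li 1 to 4 it was -1.94, -2.03, -1.41 and -1.43 in bone and -1.95, -1.87, -1.51 and -1.12 in gingiva.

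Of 12 nasal gland genes tested, 0 were called between groups in bone (edgeR). In gingiva 0 rose, and 1 fell between LiTra and Co, 2 between LiTra and Tra and 0 in the others.

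In gingiva, libraries 1 and 2 of Li and of Tra stood apart from libraries 3 and 4. The second principal component was 8.04, 31.95, -12.7 and -27.2 in Li 1 to 4 and 74.4, 41.5, -65.3 and -43.0 in Tra 1 to 4, and the fits ignored this division, which was seen in these data and is in no label, so tests on it carry little weight. A library batch shared by both groups is a candidate explanation that this test does not single out: the differences of Li and of Tra correlated across genes with r = 0.361, but those of Co gave -0.313 with Li and -0.462 with Tra. Another time of day is another candidate, as the clock index differed by 0.920 in gingiva and 1.09 in the bone libraries of the same names, 118% as much. Both stay open, and no biological explanation was tested.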
